A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

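RNA was measured in 6 cell pellets of Saccharomyces cerevisiae, 3 libraries of a β-carotene-producing strain and 3 of its parent CEN.PK2-1C, a haploid laboratory strain with several auxotrophies. Per the labels' protocols, cells grew in YPD, a rich glucose medium, for 18 h with shaking at 30 °C, RNA was extracted with a column kit and stranded mRNA libraries were made for DNBSEQ sequencing. The genotype label of the producer is CrtI/E/YB, after genes of carotenoid synthesis (phytoene desaturase, geranylgeranyl diphosphate synthase and the enzyme with phytoene synthase and lycopene cyclase activities). The genes tested here are those of the yeast annotation, and transcripts of the introduced genes were not analysed here.

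The deposited values are estimated counts per gene, written as whole numbers, 1 table for each library. Per the file headers, they come from StringTie transcript files made after duplicate reads were removed. Per the submitters' processing notes, FastQC, HISAT2, SAMtools, Picard and DESeq2 were used with the genome build sacCer3. Versions and parameters are not given in the sources used here. Counts of this kind are computed from coverage, gene length and a read length, so they are estimates rather than tallies. Duplicate removal may lower the values of abundant transcripts, which could not be tested here, and the 50 most abundant genes held between 10.0% and 11.4% of the counts in each library. Whether the counting used strand is not given in the sources used here, so overlapping and convergent genes are treated as uncertain.

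The tables list 6445 genes each, in different orders, and were joined by gene name. Of these names, 6213 matched the RefSeq annotation of the yeast reference assembly, the assembly that sacCer3 is drawn from, by symbol, locus tag or synonym, and 232 did not. Coordinates, gene GC content and upstream sequence come from that match. The values were already whole, so the rounding required for estimated counts changed nothing.

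Libraries held 56.8, 58.3 and 57.0 M counts (M, 1e6) in the producer and 57.5, 48.7 and 48.4 M in the parent. At this depth counting error is small beside the spread between libraries except for genes near 0. Intervals on counts cover counting error only.

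The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with filterByExpr, TMM scaling, robust dispersion estimation and the group as the only term. Benjamini-Hochberg adjustment ran over the 6125 genes tested, and an adjusted p under 0.05 counted as passing. The standard error of a log2 fold change is its size divided by the square root of F. CPM values were scaled by TMM. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 47 of 48 lists with at least 3 tested members. Camera with an estimated correlation and the rotation test fry were run beside it. Camera was also run on 16 chromosomes. For each list the number of members passing is given over all genes and adjusted over the list alone.

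The main test, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule names up to 12 higher and up to 12 lower genes with an adjusted p under 0.05, a change of at least 2-fold, groups that do not overlap in log2 CPM, a mean of at least 10 CPM in 1 group and a standard name, which gave 8 higher and 2 lower genes. It also names every member of the mevalonate, ergosterol and auxotrophic marker lists. Of any other list described, it names up to 4 members with the smallest adjusted p, with up to 2 more of its abundant members. Members named for their small p are the extremes of their list in these data and do not stand for the whole list. Genes named outside the rule are said to be so.

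Alternatives set in advance were other scalings (RLE factors, upper-quartile factors, library totals only, factors without the 50 most abundant genes), no filter, a filter of at least 10 CPM in 3 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0 and limma-voom. After the data were seen, a fit with the log2 library total as a covariate and a fit with a GC-content correction were added. The correction took a loess trend of log2 CPM against gene GC content (span 0.5, genes of at least 5 CPM) out of each library as an offset, for the 6066 genes, 99.0% of those tested, with a known GC content.

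The main test was run on simulated counts drawn from the means, totals and dispersions of these libraries for the producer and parent comparison. The dispersions were those of the trend over expression level, without scatter between genes, and the 200 genes changed had at least 10 CPM. Recovery in the real libraries may be lower. Over 6115 genes, 30 of 50 genes were recovered at 1.25-fold, 48 of 50 at 1.5-fold and 50 of 50 at both 2-fold and 4-fold, with 15 false calls among 193. When the GC trends of the 6 libraries were put into the simulated counts, 181 of 342 calls over 6066 genes were false without the correction and 9 of 179 with it. With the correction, 22 of 50 genes were recovered at 1.25-fold, 48 of 50 at 1.5-fold and 50 of 50 at 2-fold and 4-fold. The trends put in were those that the correction itself fits, so its success in this run was expected. The dispersions came from the uncorrected libraries and already held spread from these trends. The shares of false calls with GC trends therefore do not carry over to the real libraries. Of 40 random lists in simulated counts, camera called 0, and it called the 1 list that had been raised. The simulated genes were drawn independently, so this run says nothing about lists whose genes move together. Gal4 sites were searched as CGG and CCG separated by 11 bases, on either strand, within 500 bp upstream of each coding sequence. Exact tests were run in scipy 1.17.1.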

Results

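Transcript levels of a β-carotene-producing strain of budding yeast were set against those of its parent, CEN.PK2-1C, with 3 libraries for each strain. The producer libraries held 56.8, 58.3 and 57.0 M estimated counts (M, 1e6) and the parental libraries 57.5, 48.7 and 48.4 M, so parental replicates 2 and 3 were the shallower ones. All pairs of libraries differed by more than sampling noise, and all 6 were kept as separate samples. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The comparison asks which genes of the host differed between the engineered strain and its parent after 18 h of growth in glucose medium.

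The clearest difference lay in the galactose regulon, although the medium was not a galactose medium. GAL80, the repressor that holds Gal4 inactive (YML051W, chromosome XIII, 171594 to 172901, plus strand), had 0, 0 and 2 counts in the producer libraries and 6267, 4941 and 4891 in the parental ones. In CPM this was 0.0118 ± 0.0204 (SD, n = 3) against 102 ± 7.46 (SD, n = 3), and the pooled counts, scaled for library size, gave a parent to producer ratio of 8676 (95% exact binomial interval 2401 to 71643). The genes of galactose uptake and use rose together. GAL7, the uridylyltransferase of the pathway, went from 23.9 ± 2.88 to 1611 ± 126 CPM (SD, n = 3), a log2 fold change of 6.08 ± 0.14 (SE), and GAL1, galactokinase, from 29.9 ± 3.29 to 1642 ± 182 CPM, a log2 fold change of 5.78 ± 0.15. GAL10, the epimerase, rose by 5.62 ± 0.13 on the log2 scale to 2350 CPM. GAL2, the galactose permease, rose by 5.70 ± 0.16 to 2313 CPM. GAL3, the galactose sensor, rose by 3.35 ± 0.08 to 251 CPM. Duplicate reads were removed before counting, so folds of abundant genes may be too small, which was not tested.

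In this list of 10 galactose genes, 5 rose, 1 fell and 4 did not pass the test over all genes, while 7 rose and 1 fell when adjusted over the list alone. GAL4, the activator itself, had a log2 fold change of 0.12 ± 0.07, GCY1, a reductase, 0.57 ± 0.15, LAP3, a peptidase, 0.50 ± 0.16, and PGM2, phosphoglucomutase, 0.22 ± 0.10. This list is given in full, which goes beyond the naming rule. In edgeR's quasi-likelihood test the adjusted p was 1.71e-08 for GAL80 and between 2.50e-08 and 5.20e-08 for the 5 raised genes. Each of these 6 genes passed under all 17 alternative settings, and in each the 3 libraries of one strain lay above all 3 of the other. The list had a median log2 fold change of 1.96 with a camera adjusted p of 6.86e-09, and adjusted p = 0.252 with an estimated correlation. The fry rotation test gave an adjusted p of 2.31e-05 for it.

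**Figure D1:**
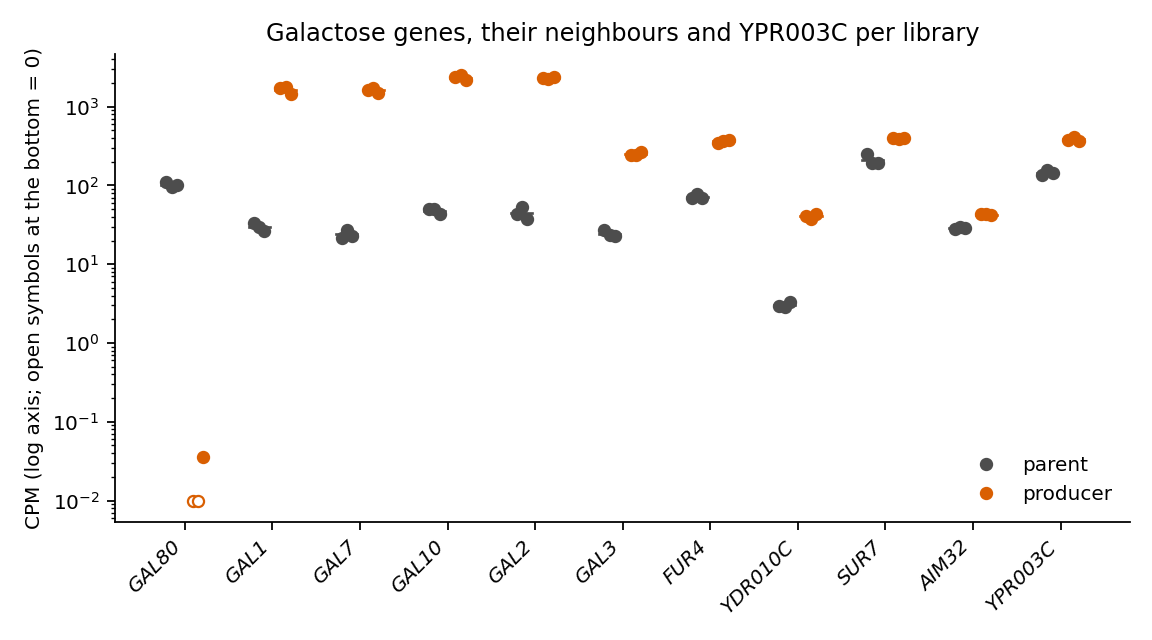
Transcript level in CPM (log axis) of the galactose genes, 4 of their neighbours and YPR003C in each of the 3 parental (grey) and 3 producer (orange) libraries, with horizontal lines at the group means and open symbols for 0 counts. GAL80 is at 0, 0 and 0.035 CPM in the producer libraries, and GAL7 lies between 1476 and 1726 CPM there against 21.5 to 27.1 CPM in the parent.

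Several genes lying next to the changed galactose genes were higher in the producer as well. FUR4, the uracil permease (chromosome II, 281443 to 283344), starts 835 bp past the end of GAL1 on the same strand and went from 72.2 ± 4.34 to 363 ± 20.4 CPM (SD, n = 3), a log2 fold change of 2.33 ± 0.08. YDR010C, a short reading frame (chromosome IV, 465051 to 465383, minus strand), ends 54 bp from the end of GAL3 and faces it, and rose from 3.06 to 41.0 CPM, a log2 fold change of 3.74 ± 0.12. Reads of these convergent genes may not be separable here, since the use of strand in counting is not stated. On both sides of GAL80, SUR7, a plasma membrane protein of eisosomes, rose by 0.90 ± 0.10 (SE) and AIM32, a mitochondrial protein, by 0.56 ± 0.08, with edgeR adjusted p values of 0.00512 and 0.0135. The genes beyond them, YML053C at -0.33 ± 0.23 and RSE1 at -0.07 ± 0.06, did not pass. KAP104, past the end of GAL7, was at -0.02 ± 0.08 and SRL2, past the end of GAL2, at -0.45 ± 0.10, and neither passed. YDR010C, SUR7, AIM32 and the 4 flanking genes were named after their values were seen.

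All 6 GAL genes just described have at least 1 consensus Gal4 site within 500 bp upstream. Of the 44 other genes called higher and searched, HTC1 and SDD1, named after their values were seen, had one, against 167 of the remaining 5870 (Fisher's exact test, two-sided, p = 0.36). FUR4, YDR010C, SUR7, AIM32 and YPR003C had 0 such sites within 1000 bp.

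Across the transcriptome, 70 of 6125 tested genes passed, 49 higher and 21 lower in the producer, and 13 of them changed at least 2-fold, 11 upward and 2 downward. Besides the genes above, the named genes with changes of this size were TIS11, an mRNA-binding regulator of the iron response (1.01 ± 0.12), COS12, of a subtelomeric family (1.08 ± 0.14), and IZH4, a membrane protein linked to zinc (-1.17 ± 0.21). COS12 has close relatives that may share its reads, and IZH4 had an edgeR adjusted p of 0.0415, or 0.0515 after the GC-content correction. YPR003C, a putative sulfate transporter without a standard name, rose from 146 ± 11.8 to 390 ± 25.4 CPM (SD, n = 3), a log2 fold change of 1.42 ± 0.08 with an edgeR adjusted p of 3.01e-05. YNL284C-A, a transposon reading frame with many near-identical copies, was at 1.21 CPM against 0.111 CPM and is uncertain. YPR003C and YNL284C-A were named after their values were seen. Of all tested genes, 33.8% had groups that did not overlap. The 10% expected for a gene with exchangeable libraries is no yardstick here, since genes moved together with the GC-content trends given below. In edgeR 1673 genes had an unadjusted p under 0.05, and 1176 after the GC-content correction. The count of 70 became 1077 without parent replicate 1, and 22, 15, 21 and 16 without producer replicate 1, 2 or 3 or parent replicate 3. DESeq2 called 842 genes and limma-voom 64, and 10 genes passed under every setting: GAL1, GAL2, GAL3, GAL7, GAL10, GAL80, FUR4, SUR7, YDR010C and YPR003C.

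The libraries also differed in how transcript level followed the GC content of the gene. Across 6070 genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.641 with GC content, and the difference of parent replicate 1 from the other parental libraries had the same correlation of 0.641. Relative to the mean of all libraries the correlation was 0.603, 0.472 and 0.327 in the producer and 0.221, -0.647 and -0.469 in the parent. On the first principal component, which held 60.1% of the variance, the producers lay at 14.6, 13.3 and 10.3 and the parents at -3.70, -21.7 and -12.8. With the GC-content correction, chosen after seeing the data, edgeR called 73 genes, 47 higher and 26 lower, and 50 of them were among the 70. GAL1, GAL2, GAL3, GAL7, GAL10, GAL80, FUR4, YDR010C, SUR7, AIM32, YPR003C, TIS11 and COS12 were among those 50.

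**Figure D2:**
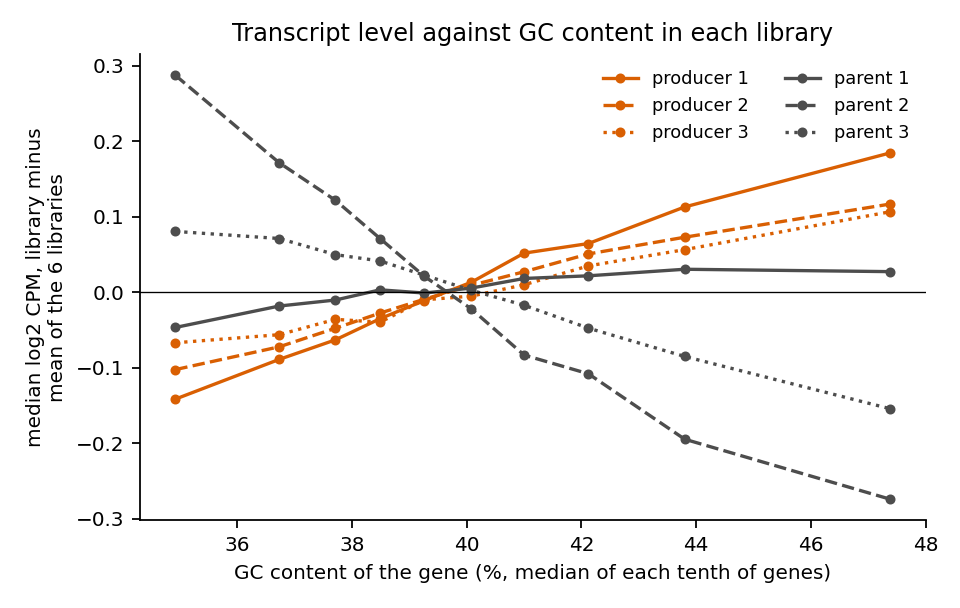
Median log2 CPM of each library minus the mean of the 6 libraries (vertical axis) in 10 bins of genes ordered by GC content (horizontal axis, median GC content of each bin in percent), producers in orange and parents in grey. In the bin of highest GC content the producer medians are 0.18, 0.12 and 0.11 and the parental ones 0.03, -0.27 and -0.15.

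The mevalonate pathway, which supplies the isoprenoid precursors of carotenoids and sterols, showed no gene past the threshold in the main fit. Under the 17 alternative settings ERG10 and ERG13 each passed in 1, and the other members in none. Of its 10 genes, 0 passed in edgeR over all genes and 0 when adjusted over the list alone. ERG10, acetoacetyl-CoA thiolase, was at 0.28 ± 0.11 (SE), ERG13, HMG-CoA synthase, at 0.30 ± 0.13, and the HMG-CoA reductase genes HMG1 and HMG2 at 0.01 ± 0.09 and -0.04 ± 0.08. ERG12 was at -0.06 ± 0.07, ERG8 at 0.15 ± 0.08, MVD1 at 0.12 ± 0.09 and IDI1, isopentenyl diphosphate isomerase, at -0.19 ± 0.07. ERG20, farnesyl diphosphate synthase, was at 0.13 ± 0.09, and BTS1, the geranylgeranyl diphosphate synthase of the host, at -0.06 ± 0.11. The 95% intervals of HMG1 (-0.20 to 0.22), ERG20 (-0.07 to 0.32) and BTS1 (-0.30 to 0.19) exclude changes of 1.5-fold. The list median was 0.07 with a camera adjusted p of 0.496. ERG10, ERG13 and IDI1 had unadjusted intervals that did not span 0, and after the GC-content correction ERG10 was at 0.12 ± 0.07, ERG13 at 0.31 ± 0.12 and IDI1 at -0.06 ± 0.06.

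The 16 ergosterol genes downstream of the branch point gave 0 members past the threshold in edgeR over all genes and 5 higher when adjusted over the list alone. These were ERG4 at 0.50 ± 0.13 (SE), ERG2 at 0.38 ± 0.11, ERG3 at 0.37 ± 0.10, NCP1 at 0.34 ± 0.11 and ERG27 at 0.29 ± 0.09. Each of these 5 passed over all genes in 2 of the 17 alternative settings, and the other members in none. With the GC-content correction ERG4 was at 0.44 ± 0.10, ERG2 at 0.22 ± 0.07, ERG3 at 0.24 ± 0.07, NCP1 at 0.10 ± 0.06 and ERG27 at 0.23 ± 0.07. ERG9, squalene synthase at the branch itself, was at 0.17 ± 0.11, ERG1 at 0.10 ± 0.09, ERG7 at 0.09 ± 0.06 and ERG11 at 0.03 ± 0.10. ERG24 was at 0.07 ± 0.10, ERG25 at 0.09 ± 0.08, ERG26 at -0.06 ± 0.07, ERG28 at -0.03 ± 0.10, ERG29 at -0.07 ± 0.08, ERG6 at 0.00 ± 0.08 and ERG5 at 0.00 ± 0.08. The ergosterol list had a median of 0.09 and a camera adjusted p of 0.0418, and adjusted p = 0.856 with an estimated correlation. Corrected for GC content, the ergosterol list had a median of 0.07 with a camera adjusted p of 0.0490, and adjusted p = 0.839 with an estimated correlation. With the library total as a covariate the ergosterol median was -0.0080 with a camera adjusted p of 0.717. Of the 4 auxotrophic marker genes, 0 passed in edgeR, over all genes or over the list alone. HIS3 was at 0.61 ± 0.29 (0.33 ± 0.24 after the GC-content correction), TRP1 at 0.18 ± 0.08, LEU2 at 0.13 ± 0.14 and URA3 at 0.10 ± 0.09.

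**Figure D3:**
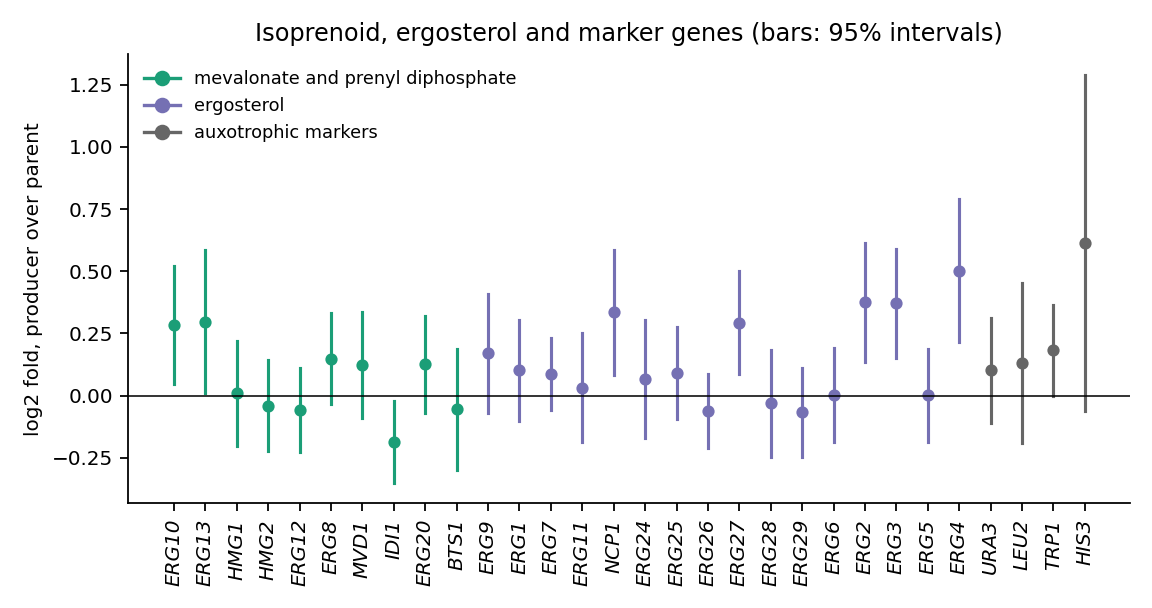
Log2 fold change of producer over parent (vertical axis) with 95% intervals from the edgeR fit for the mevalonate and prenyl diphosphate genes (green), the ergosterol genes (purple) and the auxotrophic markers (grey), 3 libraries per strain. Point estimates run from -0.19 for IDI1 to 0.50 for ERG4 among the pathway genes, and HIS3 has the widest interval, -0.06 to 1.29.

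Some genes of iron uptake and the response to low iron were higher in the producer. TIS11, whose product promotes decay of mRNAs of iron-using proteins, rose from 80.8 ± 13.8 to 163 ± 8.43 CPM (SD, n = 3), SMF3, a vacuolar metal transporter, by 0.48 ± 0.08 (SE) on the log2 scale, and FRE3, a reductase for siderophore-bound iron, by 0.45 ± 0.07. Of the 26 tested members, 3 rose, 0 fell and 23 did not pass in edgeR over all genes, and 18 were higher when adjusted over the list alone. FIT3, a cell wall mannoprotein that retains siderophores, was at 1.16 ± 0.26, SIT1, a siderophore transporter, at 1.00 ± 0.22 and FET3, the ferroxidase of high-affinity uptake, at 0.71 ± 0.16, with adjusted p of 0.0698, 0.0659 and 0.0667. FIT3 was named outside the rule. Over the list the median was 0.29, with a camera adjusted p of 2.55e-07, and adjusted p = 0.758 with an estimated correlation. The fry test gave an adjusted p of 0.0899 for it. Relative to the mean of the libraries the list stood at 0.20, 0.19 and 0.13 in the producer and at -0.04, -0.31 and -0.14 in the parent, and after the GC-content correction its median was 0.28.

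Some genes of sulfur amino acid metabolism were higher too. MMP1, the permease for S-methylmethionine, rose by 1.00 ± 0.11 (SE), CYS3, cystathionine gamma-lyase, by 0.79 ± 0.14 (0.49 ± 0.08 after the GC-content correction), MET17, which incorporates sulfide, by 0.55 ± 0.10, and MHT1, the S-methylmethionine methyltransferase encoded beside MMP1 on chromosome XII, by 0.50 ± 0.09. Of the 26 members, 4 rose, 0 fell and 22 did not pass in edgeR over all genes, and 11 were higher when adjusted over the list alone. SAM1, an S-adenosylmethionine synthetase, was at 0.86 ± 0.19 with an adjusted p of 0.0687, and MUP1, the high-affinity methionine permease, at 0.62 ± 0.13 with 0.0609 (0.0466 after the GC-content correction). SAM1 was named outside the rule, and MET6, named by it, was at 0.25 with an edgeR adjusted p of 0.583. The list median was 0.32 with a camera adjusted p of 2.89e-06, and adjusted p = 0.758 with an estimated correlation. The fry test gave it an adjusted p of 0.0673. The list stood at 0.17, 0.16 and 0.12 in the producer and at -0.05, -0.25 and -0.13 in the parent, and its median was 0.23 after the GC-content correction and 0.16 with the library total as a covariate. TIS11, SMF3, FRE3, MMP1, CYS3, MET17 and MHT1 each lost their call in at least 1 of the 17 settings. None of them changed direction in any setting, but the strains did not overlap in these genes, which leaves little room for that.

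**Figure D4:**
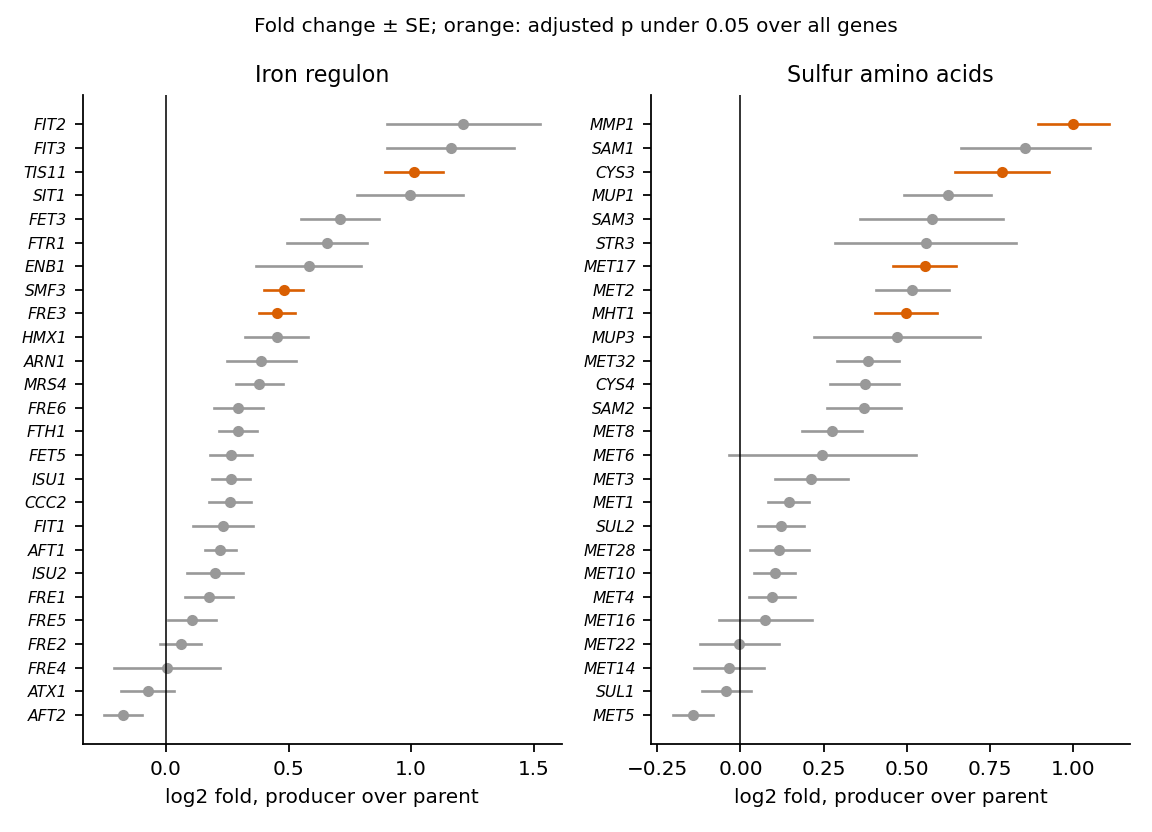
Log2 fold change of producer over parent ± SE (horizontal axis) for the 26 iron regulon and 26 sulfur amino acid genes, 3 libraries per strain, with genes past the edgeR threshold over all genes in orange. Of the plotted genes, 24 in the iron list and 22 in the sulfur list lie above 0.

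Hexose transporters changed in both directions. Besides GAL2, HXT13 rose by 0.69 ± 0.12 (SE) and HXT17 by 0.79 ± 0.14, members of a near-identical group whose reads may be shared, while HXT5, a transporter of slow-growing cells, fell by 0.63 (SE 0.11) and HXT4 fell by 0.44 (SE 0.08). HXT4 was named outside the rule. Of the 23 tested members, 3 rose, 2 fell and 18 did not pass in edgeR over all genes, against 4 higher and 4 lower when adjusted over the list alone. The abundant HXT6 and HXT7, at 3068 and 3476 CPM in the producer, were at -0.02 ± 0.12 and -0.04 ± 0.12. For the whole list the median was 0.03, with a camera adjusted p of 0.523.

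The fixed lists hold 3 groups of cell surface genes. The cell wall list had 0 of 30 members past the threshold in edgeR over all genes and 1 lower when adjusted over the list alone, with a median of 0.07 and a camera adjusted p of 0.726. After the GC-content correction its median was -0.13 with a camera adjusted p of 0.0217, and adjusted p = 0.839 with an estimated correlation. In the list of anaerobic wall and sterol uptake genes, TIR2 and TIR1, mannoproteins of the TIR family, rose by 0.75 ± 0.12 (SE) and 0.69 ± 0.12, 0 fell and 10 of 12 did not pass in edgeR over all genes, with 4 higher when adjusted over the list alone. After the GC-content correction TIR2 was at 0.49 ± 0.08, and TIR1 at 0.43 ± 0.10 with an edgeR adjusted p of 0.0808. Its list had a median of 0.20 with a camera adjusted p of 0.00200, and adjusted p = 0.758 with an estimated correlation. Another split of the libraries into 3 and 3 reached 0.26, against 0.21 for the real one. In the flocculation and adhesion list, AGA1, the anchor of a-agglutinin, rose by 0.54 ± 0.09, 9 of 10 did not pass over all genes, and 3 were higher when adjusted over the list alone. FLO5 was at 0.51 ± 0.12 and FLO11 at 0.49 ± 0.20, both of a family with repeated sequence, and FLO11 was at 0.24 ± 0.20 after the GC-content correction. The list median was 0.34 with a camera adjusted p of 0.00200, and adjusted p = 0.715 with an estimated correlation, and 0.20 after the correction.

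Other lists held few called genes. In the oxidative stress list, OYE3, an NADPH oxidoreductase, rose by 0.96 ± 0.15 (SE) and MXR1, a methionine sulfoxide reductase, by 0.37 ± 0.06, and 35 of 37 did not pass in edgeR. CTT1, the cytosolic catalase, was at -0.11 ± 0.14 and SOD1, named outside the rule, at 0.22 ± 0.12. Adjusted over the list alone, 3 were higher and 2 lower. That list had a median of 0.14 and a camera adjusted p of 0.0455, and adjusted p = 0.856 with an estimated correlation, and its median after the GC-content correction was 0.04. The nitrogen catabolite list had 0 of 27 members past the threshold in edgeR, 11 higher and 2 lower when adjusted over the list alone, and a median of 0.25 with AGP1, a broad amino acid permease, at 0.57 ± 0.12. Its camera adjusted p was 0.00200, and adjusted p = 0.758 with an estimated correlation, and after the GC-content correction its median was 0.09 with a camera adjusted p of 0.0722. In the list of beta-oxidation and peroxisome genes, POX1, acyl-CoA oxidase, fell by 0.53 (SE 0.09), 28 of 29 did not pass, and 6 were lower when adjusted over the list alone. FOX2 was at -0.36 ± 0.09, and at -0.41 ± 0.07 with an edgeR adjusted p of 0.0324 after the GC-content correction. The list median was -0.09 with a camera adjusted p of 0.0241, and adjusted p = 0.758 with an estimated correlation. Efflux genes of the pleiotropic drug resistance list gave 0 of 21 past the threshold in edgeR, and 0 adjusted over the list alone, with PDR5, named outside the rule, at 0.00 ± 0.10 and TPO1 at 0.51 ± 0.15 (0.34 ± 0.11 after the GC-content correction). Its median was -0.03 with a camera adjusted p of 0.666.

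Of the genes of ribosome synthesis, few passed. ESF1, a factor of small subunit processing, fell by 0.39 (SE 0.07) and was the 1 of 46 ribosome biogenesis genes to pass in edgeR over all genes, and the 1 lower when adjusted over the list alone. After the GC-content correction ESF1 was at -0.29 ± 0.06 with an edgeR adjusted p of 0.0569, and 0 of the list passed. Its list had a median of -0.13 and a camera adjusted p of 0.00811, with adjusted p = 0.856 with an estimated correlation, and -0.07 after the correction. With the library total as a covariate the ribosome biogenesis median was -0.04 with a camera adjusted p of 0.326. RPS25B fell by 0.40 (SE 0.07), 1 of 138 ribosomal protein genes, which are mostly close paralog pairs, and 0 passed when adjusted over the list alone. Their median was -0.07 with a camera adjusted p of 0.0111, and adjusted p = 0.856 with an estimated correlation, and after the GC-content correction -0.04 with a camera adjusted p of 0.00262, adjusted p = 0.934 with an estimated correlation, and 3 genes lower. The strains overlapped in both lists: ribosome biogenesis stood at -0.20, 0.07 and -0.06 in the producer and at -0.04, 0.13 and 0.08 in the parent, and ribosomal proteins at -0.07, 0.07 and -0.10 against 0.11, -0.08 and 0.06. Other splits of the libraries into 3 and 3 reached medians of 0.19 and 0.16 in size, against 0.13 and 0.07 for the real one. In the heat shock list HSP26, a small chaperone, fell by 0.63 (SE 0.11), 31 of 32 did not pass, and 2 were lower when adjusted over the list alone, with a median of -0.05 and a camera adjusted p of 0.233. After the GC-content correction its median was -0.18 with a camera adjusted p of 2.85e-04, and adjusted p = 0.839 with an estimated correlation, and another split reached 0.20 in size against 0.17 for the real one.

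In all, 17 of 47 testable lists passed with camera, 14 higher and 3 lower, 0 with an estimated correlation, where 19 had an unadjusted p under 0.05 with the preset correlation, and 2 in fry, the galactose and pyrimidine lists. In the pyrimidine list FUR4 rose and 13 of 14 did not pass in edgeR. The higher lists not described above were seripauperins, pentose phosphate, vitamins B1 and B6, maltose, glycerol and osmotic response, and amino acid synthesis, in which 0 genes passed in edgeR over all genes, and their medians lay between 0.11 and 0.20. Of these 6 lists, 0 passed with camera after the GC-content correction, and 14 of the 47 passed in all, 0 of them with an estimated correlation. None of the 16 chromosomes passed with camera, which gave 3 at an unadjusted p under 0.05, or with an estimated correlation, and fry gave 3. Chromosome I had the lowest adjusted p, 0.0680, and a median of 0.09, and it passed at 0.0287 without parent replicate 1.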

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

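Genes and lists counted as passing depended on the libraries used, and the depth of 48.4 to 58.3 M counts (M, 1e6) limits only genes near 0. No called gene changed direction under the alternatives that tested it (17, or 15 for YNL284C-A and 16 for YOL163W). In all 70 the strains did not overlap, which leaves little room for such a change, above all with 1 library left out. Of the genes, 10 passed under all 17, and 5 lists (galactose, iron, sulfur amino acids, anaerobic wall, flocculation) passed under the 15 run for lists with camera's preset correlation. From 70, the number of genes passing became 10 with the library total as a covariate, 842 with DESeq2 and 15 to 1077 with 1 library left out. Those changed at least 2-fold, 13, became 10 to 34 with 1 library left out, and the 73 with the GC-content correction became 23 to 131. Lists passing, 17, became 0 with an estimated correlation and 2 with fry. The covariate and the GC-content correction were chosen after seeing the data. Replicates with the same number did not deviate together (correlations 0.238, -0.231 and -0.459). With a replicate block 104 genes passed, 59 of them shared, and 1 chromosome (I, adjusted p 0.0316 with camera) in place of 0. With 1 library left out, 0 to 1 chromosomes passed. The amino acid synthesis median, 0.11, became -0.0358 with the covariate and between -0.0043 and 0.22 with 1 library left out. With the GC-content correction the camera direction reversed for oxidative stress (median 0.0374), the tricarboxylic acid cycle (-0.0932) and the cell wall (-0.132), each passing in 1 of the 2 fits and in neither with an estimated correlation. It also turned for hexose transport, pyruvate and ethanol, lipid droplets and autophagy, which passed in neither. The cause was not tested for these changes. Leaving out a library leaves fewer samples, which would not by itself raise the count to 1077 without parent replicate 1. That library had a GC-content correlation of 0.221, against -0.647 and -0.469 in the other parents. With the GC-content correction no count with 1 library left out exceeded 131.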

Other observations

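Other genes past the threshold, chosen after their values were seen and not tested as groups, changed in both directions. MRH1, a membrane protein, fell by 0.78 (SE 0.12), its paralog YRO2 fell by 0.92 (SE 0.16), PUN1 fell by 0.92 (SE 0.13), and AQR1, a multidrug transporter of the major facilitator family, fell by 0.62 (SE 0.08). BIO2, biotin synthase, fell by 0.60 (SE 0.08). OPT1, an oligopeptide transporter, rose by 0.43 ± 0.07 (SE; edgeR adjusted p of 0.0569 after the GC-content correction), HBN1, a putative nitroreductase, by 0.69 ± 0.09 (0.45 ± 0.07 corrected), and AAD4, an aryl-alcohol dehydrogenase of a paralog family, by 0.47 ± 0.08.

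With the GC-content correction, chosen after seeing the data, the glycolysis list had a median of -0.18 with a camera adjusted p of 6.39e-05, and adjusted p = 0.307 with an estimated correlation. Without the correction its median was -0.01 with a camera adjusted p of 0.644, and with the library total as a covariate the glycolysis list had -0.12 with 0.0284. Its genes had a median GC content of 45.1%, where the correction lowers the producers relative to the parents. Whether the correction takes out too much there was not tested. The corrected list stood at -0.06, -0.05 and -0.28 in the producer and at 0.10, 0.08 and 0.14 in the parent. TDH2, a glyceraldehyde-3-phosphate dehydrogenase, was at -0.57 ± 0.09 (SE) and TIP1, a cell wall mannoprotein, at -0.65 ± 0.07. In the uncorrected edgeR fit TDH2 was at -0.30 and TIP1 at -0.37 and neither passed.

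All of the tests below were chosen, and their predictions written, after the results they bear on had been seen. FUR4, YDR010C, SUR7 and AIM32 lie beside GAL genes and were higher in the producer. In the reference genome 0 of these 4 genes have a consensus Gal4 site within 1000 bp upstream. This argues against a site of that form where the strains share the reference sequence. The sequences of the producer and of its parent were not searched. A site absent from the reference but present in the producer, or in both strains, is not excluded. Transcription running on past GAL1 and GAL3 cannot be told from other causes for FUR4 and YDR010C. The gain of FUR4 was 18.0% of that of GAL1 and the gain of YDR010C 16.8% of that of GAL3. These are gains in CPM, not scaled for gene length. YDR010C (465051 to 465383) is much shorter than GAL3 (463434 to 464996), so per base its share is larger than 16.8%. However, KAP104, past the end of GAL7 on the same strand, gained -0.28%, and SRL2, past GAL2, -1.13%. SRL2 and YDR010C lie on the strand opposite to their GAL gene, so they bear on this only if counting ignored strand. For AIM32, reading through from an intact GAL80 is ruled out by the 2 GAL80 counts in the 3 producer libraries together. The loss of GAL80 transcript beside raised SUR7 and AIM32 is in line with a change at that locus, which needs the strain's sequence to settle.

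For the changes under 2-fold, 57 of the 70 calls, a GC-content trend that differs between libraries is present inside the parent group, where the difference of replicate 1 from the others had a Spearman correlation of 0.641 with GC content over genes. It is not the whole cause, since 38 of the 57 calls also passed with the GC-content correction, while for the 20 calls lost in all the median size went from 0.53 to 0.31 and the median SE from 0.0905 to 0.0859. Some of these 20 kept most of their size, such as GIT1 (-0.70 and -0.62 corrected) and YOL163W (0.66 and 0.58), both named outside the rule. The library total cannot be told from the strain: with it as a covariate the median size of the 57 was 0.46, against 0.56, and the SE grew from 0.09 to 0.11, so 1 of them still passed. A difference between the strains could account for the calls that stayed, but the shallower libraries are both parental.

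The medians of the iron and sulfur amino acid lists were higher in the producer. A GC-content trend does not account for either list as a whole, since their medians were 0.28 and 0.23 after the correction. The library total cannot be told from the strain here. With it as a covariate the medians were 0.20 and 0.16, against 0.29 and 0.32 without it. Drift of the whole list between samples cannot be excluded: in the other splits of the libraries into 3 and 3 the medians reached 0.23 and 0.19, against 0.30 and 0.34 for the real one. Every other split mixes the strains unevenly, so part of a strain effect stays in it, and these medians do not measure drift alone. The galactose list reached 0.83 in another split, against 1.96 for the real one. The iron and sulfur amino acid lists both lost their calls with an estimated correlation and in fry. An effect of the strain may explain them, but labels that show separate cultures would be needed.

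With 3 and 3 libraries there are 10 splits, the real one included, too few for a share under 0.05. Every other split has both strains on each side, so a strain difference adds to the spread inside its groups. Low gene counts in those splits were therefore likely in advance. Of the 10, 1 had as many genes passing as the real 70 (highest other 1), 1 as many at least 2-fold as the real 13 (highest other 1), 3 as many lists as the real 17 (highest other 22) and 10 as many chromosomes as the real 0 (highest other 0). With the GC-content correction, 1 had as many genes as the real 73 (highest other 1) and 3 as many lists as the real 14 (highest other 16).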
